A study of Mus musculus with 23 samples.

How the data were processed

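RNA sequencing was analysed for the hippocampus of mice on a C57BL6/J background that carried both, 1 or no intact copies of Acss2, here called WT, Het and KO. Per the labels, exons 3 to 7 of the gene were deleted in single-cell embryos, so that the loss is constitutive. The labels describe 2 experiments that were analysed separately. In the first, whole hippocampi were dissected freehand from home cage mice, with 2 libraries for each of the 3 genotypes, all of batch B0. In the second, dorsal hippocampal sections were taken with a brain matrix from WT and KO mice, either straight from the home cage or 30 min after contextual fear conditioning with a single shock. The second experiment holds 5 WT home cage, 3 WT fear, 5 KO home cage and 4 KO fear libraries in batches B1, B2 and B3. Per the labels' protocols, brains were snap-frozen, RNA was extracted with Trizol, polyadenylated RNA was selected, and libraries were made with the NEBNext Ultra II RNA kit, which does not mark strand. Nothing beyond the labels shows that the replicates are separate animals, so a p-value measures the spread between these samples. Every pair of libraries of 1 group differed by more than sampling noise, with a chi-square of 5.86 to 58.9 per gene, and each library was counted as 1 replicate.

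The main measurements are the raw counts per gene symbol that the authors deposited, 24985 symbols for each experiment. The submitters' processing notes name STAR, SAMtools 1.1, HTSeq 0.9.1, DESeq2, limma and the mm10 genome build, with no role or order given; the gene annotation is not given in the sources used here. The deposited normalized signal values of whole hippocampus equal the counts divided by 1 size factor per library. The deposited normalized signal values of the dorsal experiment matched, over 12000 genes, a DESeq2 variance-stabilizing transform followed by limma's removal of batch with the groups kept. The median absolute log2 difference was 1.73e-09, against 0.0431 with the groups left out. Adjusted values of that kind were used only in checks of the deposited values, and not in the tests reported here. Of the dorsal symbols, 26 had been turned into dates and could not be matched. GENCODE release M21 on mm10 held 98.2% of the whole hippocampus symbols and 98.1% of the dorsal ones, and its coordinates are printed 1-based. Haemoglobin genes carried 3 reads in the whole hippocampus table and 2 in the dorsal table.

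Library totals ran from 18814460 to 27293661 counts in whole hippocampus and from 5362773 to 23412644 in the dorsal experiment. Batch B1 held 5362773 to 9109104 counts per library, B2 18346424 to 23412644 and B3 14054430 to 19136156, and each WT fear library came from B1. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 0 reads in every library of a group was set to 3 counts per library, and folds against it are lower bounds.

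Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, after TMM normalization and filterByExpr with a count minimum of 10 and a total minimum of 15. The filter left 15453 genes in whole hippocampus and 14808 in the dorsal experiment. Whole hippocampus was fitted on its 6 libraries with a term for genotype and 3 residual degrees of freedom. The dorsal experiment was fitted on its 17 libraries with terms for group and batch and 11 residual degrees of freedom. The interaction of genotype and fear was the KO fear difference minus the WT fear difference. Adjusted p-values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. CPM values are edgeR's counts relative to the TMM-scaled library size, given as mean ± SD. Log2 fold changes are given with ± an approximate standard error. This error is the size of the log2 fold change divided by the square root of its F statistic. It is uncertain for genes with few reads.

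A total of 33 gene lists of pathways, cell types and brain regions was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation, and fry, were run beside it. The list of genes encoded by mitochondrial DNA had 0 members in the tables, so 256 list tests were made. Camera at the preset correlation called 90 of them, camera with an estimated correlation 4 and fry 35. In 33 of the 256 tests a list's median, mean and camera direction differed in sign, and camera called 0 of those 33. Ribosomal protein genes have many near-identical pseudogene copies, so their counts are uncertain. Acss2 overlaps Acss2os, Ggt7 and Gss on the opposite strand, and reads of a gene and its antisense partner cannot be told apart in libraries without strand. The same holds for Junb with Prdx2, Amigo2 with Pced1b and Xist with Tsix. It holds for further named genes too, among them Arg2 with Vti1b, Phkg1 with Sumf2, Fam117b with Ica1l and Sf3a2 with Plekhj1. Others are Dnah11 with Cdca7l, Alas2 with Apex2, Zrsr1 with Commd1 and Dusp1 with Ergic1.

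The sample groups, comparisons, tests, gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. Acss2 was named in each comparison. In KO against WT whole hippocampus, in the fear comparison of each genotype, in KO against WT home cage and in the interaction, up to 10 higher and 10 lower genes with the smallest p among those passing were named; in the other 3 comparisons up to 4 each. Unnamed gene models were skipped. Where fewer than 3 genes besides Acss2 passed, the 5 with the smallest p were named as not passing. Of each list spoken of, up to 4 members with the smallest p were named, apart from an item withheld from the text. In the fear comparisons and the interaction Fos, Arc, Npas4, Egr1, Junb, Nr4a1, Dusp1, Bdnf, Fkbp5 and Sgk1 were named in every case.

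Alternatives covered scaling by relative log expression (RLE), no count filter, robust dispersions, the replicate number as a block, DESeq2 1.42.0, fits of single groups or batches, no batch term, and each library left out in turn. Others were chosen after seeing the data: tissue marker scores as covariates, an offset for GC content and gene length, libraries thinned to equal depth, fits without X and Y genes, a choroid plexus score, crossed replicate numbers, fits without B1, and the interaction along 2 routes within batches. The tissue covariates were the CA1 marker score minus the CA2 and CA3 marker score, and the sum of the oligodendrocyte and ependymal scores. After a first run, the genes behind the scores were left out of 1 tissue test and the delayed activity list was put back into another, which changed no outcome; a condition that the standard error grow less than 2 times was set in the code before the errors were seen but not in the written prediction. The comparison of WT fear genes with the KO libraries of B3 was first made with the 17-library fit, whose batch term uses those libraries, and was replaced after its result was seen.

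The edgeR fit was tested on simulated counts drawn from the mean levels, dispersions and library sizes of the real tables. It recovered 55 of 65 genes changed 2-fold in KO against WT whole hippocampus (84.6%) with 5.59% false calls, 50 of 67 in Het against WT with 4.73% and 50 of 67 in KO against Het with 15%. In the dorsal fit it recovered 48 of 66 genes changed 2-fold for WT fear (72.7%), 54 of 66 for KO fear (81.8%), 50 of 67 for KO against WT home cage, 50 of 66 for KO against WT after fear and 38 of 67 for the interaction (56.7%). False calls in these 5 were 4.07%, 5.73%, 5.73%, 9.15% and 4.31%. DESeq2, run on 2 of the simulations, recovered 56 of 65 genes in KO against WT whole hippocampus with 18.2% false calls and 51 of 66 for WT fear with 10%. A simulated rise of the astrocyte list was found by camera, with 0 of the 31 other lists called. Genes were drawn independently of each other in this simulation. It therefore does not measure false list calls where genes of a list are correlated. Nor does it measure false gene calls where libraries share a structure other than group and batch. Real dorsal libraries split otherwise than by their labels gave up to 2429 called genes in KO against WT after fear. In KO against WT home cage such splits gave up to 2361.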

Results

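ACSS2 is a nuclear and cytosolic enzyme that makes acetyl-CoA from acetate, and the series asks how acetyl-CoA metabolism bears on fear memory and on histone acetylation that follows neuronal activity. Polyadenylated RNA was counted in 23 mouse hippocampus libraries. The first experiment held 2 WT, 2 Het and 2 KO libraries of whole hippocampus, with totals of 21927140 to 22094372, 18814460 to 26739792 and 22335270 to 27293661 counts per library. The second held dorsal hippocampus of WT and KO mice in the home cage (n = 5 each) and after fear conditioning (n = 3 WT and n = 4 KO). Totals per library were 7790467 to 22388429 counts in WT home cage, 5362773 to 9109104 in WT fear, 14054430 to 23412644 in KO home cage and 7142143 to 19136156 in KO fear. WT home cage 1 and 2, the 3 WT fear libraries and KO fear 1 and 2 were of batch B1. WT home cage 3 to 5 and KO home cage 1 to 3 were of B2, and KO home cage 4 and 5 with KO fear 3 and 4 of B3.

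Acss2 RNA followed the labelled genotype in each of the 23 libraries. In whole hippocampus it stood at 60.9 and 60.3 CPM in WT, 31.2 and 34.3 CPM in Het, and 6.73 and 7.02 CPM in KO. The dorsal WT home cage libraries held 57.6, 64.7, 71.3, 66.9 and 65.6 CPM, and the WT fear libraries 57, 57.7 and 56.2 CPM. KO home cage libraries held 4.17, 4.55, 3.87, 4.89 and 5.85 CPM, and KO fear libraries 5.47, 5.18, 5.43 and 6.04 CPM. The gene (ENSMUSG00000027605.18) lies on chromosome 2 from 155517948 to 155585724 on the plus strand of mm10. The deleted exons 3 to 7 make up 460 of the 2931 bp of the 18-exon transcript Acss2-201, or 15.7%, so counts over the whole gene can also include reads of the exons that were kept. Acss2 fell by 3.14 ± 0.081 on the log2 scale in KO against WT whole hippocampus (8.81-fold, edgeR adjusted p = 4.23e-05), by 3.93 ± 0.10 in the dorsal home cage (15.3-fold, adjusted p = 6.12e-14) and by 3.54 ± 0.13 after fear (11.6-fold, adjusted p = 1.96e-11). It passed in each alternative run for these 3 comparisons. Fear conditioning gave Acss2 log2 differences of -0.15 ± 0.11 in WT and 0.24 ± 0.12 in KO, neither of which passed (edgeR adjusted p = 0.423 and 0.968).

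**Figure D1:**
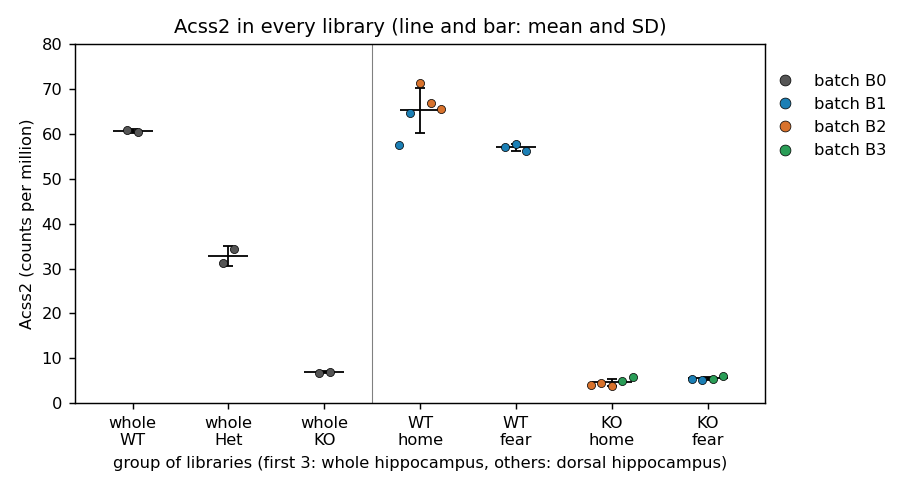
Acss2 in CPM for each of the 23 libraries by group, coloured by batch, with a line and bar for the mean and SD. KO libraries lie between 3.87 and 7.02 CPM, Het libraries at 31.2 and 34.3 CPM, and WT libraries between 56.2 and 71.3 CPM.

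KO against WT whole hippocampus asked what constitutive loss of the gene does at rest. The 6 genes that changed were Acss2 and 5 sex-linked genes. Xist, the RNA that coats the inactive X chromosome of females, fell from 670 ± 9.9 CPM in WT to 0.141 ± 0.0057 CPM in KO (SD, n = 2 each). The WT to KO ratio of Xist was 4740, with a 95% counting interval of 2300 to 11800 from 7 KO reads (exact binomial). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both WT libraries and stood at 95.3, 64, 33.5 and 21 CPM in KO, at least 693-fold, 466-fold, 244-fold and 153-fold higher against 3 counts per library. Het libraries resembled WT in these genes, with Xist at 620 ± 33 CPM and 7, 2, 1 and 0 reads of the same Y-linked genes. The sources used here give no sex, and each dorsal library of either genotype expressed the Y-linked genes, with Ddx3y from 70.5 to 120 CPM. The edgeR adjusted p was 3.31e-07 for Xist and 5.3e-05, 0.000205, 0.000971 and 0.00258 for Ddx3y, Eif2s3y, Kdm5d and Uty. Uty no longer passed without KO 1 or without KO 2, with an adjusted p of up to 0.0772.

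Among the gene lists, the sex-linked list was called higher with 4 of its 6 members higher and 1 lower, both over all genes and adjusted over the list alone. Its median log2 change was 12.3 as fitted and 7.60 with the 4 genes at their bound, and the camera call held with an estimated correlation (adjusted p = 0.00771). Oligodendrocyte markers were higher as a group, with a median log2 change of 0.27 and 14 of 15 members above 0; 0 passed over all genes by edgeR and 12 were higher adjusted over the list alone. Myelin genes led this list, with Ermn at 0.34 ± 0.052, Cldn11 at 0.33 ± 0.056, Mobp at 0.44 ± 0.088 and Mal at 0.37 ± 0.075. Its call was lost at an adjusted p = 0.197 with an estimated correlation. The glucocorticoid-induced list had a median of 0.12, led by the lipid droplet gene Plin4 at 1.00 ± 0.19 and the kinase gene Sgk1 at 0.41 ± 0.093. Of its 21 members 0 passed over all genes and 2 were higher adjusted over the list alone, and its adjusted p = 0.238 with an estimated correlation. The rapid activity-induced list was lower as a group by camera, with a median of -0.21 and 22 of 27 members below 0. None of its members, such as Junb at -0.41 ± 0.14, passed over all genes by edgeR or adjusted over the list alone, and its adjusted p = 0.964 with an estimated correlation. Blood markers, of which 2 of 7 were tested, were lower through Alas2, the erythroid haem synthesis enzyme, at -3.30 ± 0.32 and the red cell anion exchanger Slc4a1 at -3.04 ± 0.59. Both passed adjusted over the list alone and neither over all genes (list adjusted p = 0.14 with an estimated correlation). Metabolic lists were not called: the acetyl-CoA list of 30 genes had a median of 0.0041, a mean of -0.022 of the opposite sign, and an adjusted p = 0.57 by camera. In all, 941 genes had an unadjusted p under 0.05, and DESeq2 called 19 genes against 6 by edgeR. Fitted without X and Y genes, Acss2 alone was called.

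**Figure D2:**
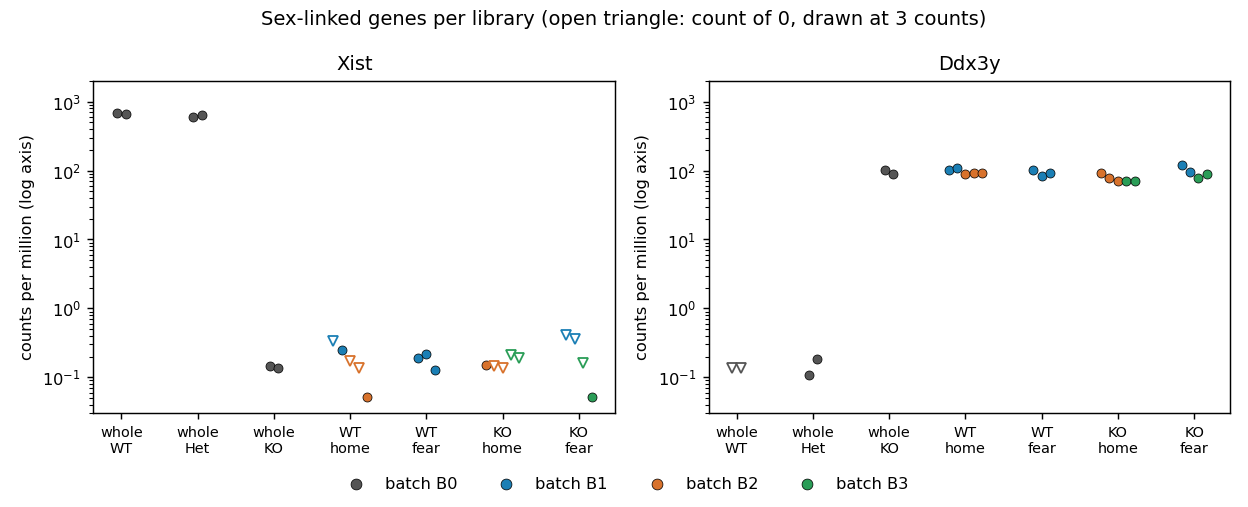
Xist and the Y-linked gene Ddx3y in CPM on a log axis for each library, coloured by batch; open triangles mark a count of 0 drawn at 3 counts. Whole hippocampus WT and Het libraries carry Xist between 597 and 677 CPM, and whole KO and dorsal libraries carry Ddx3y between 70.5 and 120 CPM.

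Het against WT whole hippocampus asked what the loss of a single copy does. Acss2 stood at 32.8 ± 2.2 CPM in Het and 60.6 ± 0.45 CPM in WT (SD, n = 2 each), a 0.541-fold level (log2 -0.89 ± 0.071). This difference did not pass by edgeR (adjusted p = 0.0777), and DESeq2 gave it an adjusted p of 3.11e-10 within a range up to 0.779 over 16 alternatives, 4 of which passed. With edgeR 0 genes passed, 2145 had an unadjusted p under 0.05, and DESeq2 called 142. The smallest p-values besides Acss2 belonged to Alas2 (-4.27 ± 0.35, adjusted p = 0.0777), the splicing factor gene Zrsr1 (0.53 ± 0.047), the potassium channel gene Kcnj2 (1.08 ± 0.11), the cold-inducible RNA-binding protein gene Cirbp (0.45 ± 0.047) and the vesicular glutamate transporter gene Slc17a6 (0.61 ± 0.067). None of them passed. Glucocorticoid-induced genes were lower as a group, with a median of -0.25. Sgk1 stood at -0.78 ± 0.095, the metallothionein genes Mt2 and Mt1 at -0.73 ± 0.10 and -0.62 ± 0.095, and the stress-induced Ddit4 at -0.63 ± 0.096. Of the 21 members 0 passed over all genes by edgeR, 9 were lower and 1 higher adjusted over the list alone, and the adjusted p = 0.146 with an estimated correlation. Neocortex markers were higher with a median of 0.80, including the deep-layer genes Tbr1 at 0.88 ± 0.19 and Foxp2 at 1.56 ± 0.48; 3 were higher and 1 lower adjusted over the list alone (adjusted p = 0.637 with an estimated correlation). The mean neocortex score was -0.0737 in Het 1 and 0.909 in Het 2, and without Het 2 the median was 0.13 and the call was lost. Dentate gyrus markers were lower with a median of -0.31 and CA2 and CA3 markers with -0.28, 0 members of either list passing adjusted over the list alone (adjusted p = 0.637 for both with an estimated correlation). Leaving out Het 1 gave 1424 called genes, and leaving out any other library gave 0 by edgeR.

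KO against Het compared 2 carriers of the deletion that also differed in their sex-linked genes. Sex and KO therefore cannot be told apart in this comparison. Besides Acss2, which fell by 2.25 ± 0.080 (4.77-fold, edgeR adjusted p = 0.000213), the called genes were again led by sex-linked ones. The ratio of KO to Het was 625 for Ddx3y (95% counting interval 303 to 1560), 1460 for Eif2s3y (404 to 12100) and 1530 for Kdm5d (274 to 60400), and Uty was at least 132-fold higher. Xist was 4430-fold higher in Het (2150 to 11000). Of the other genes, Eps8l1, an adaptor of actin signalling, fell by 3.96 ± 0.24, Kcnj2 by 1.17 ± 0.11 and Zrsr1 by 0.46 ± 0.046 (adjusted p = 0.00325, 0.0364 and 0.0448). Kcnj2 averaged 10.1 CPM in WT, 21.3 CPM in Het and 9.5 CPM in KO. Zrsr1 averaged 85.1, 122.6 and 88.9 CPM in the same order. For both genes the Het level stood above WT and KO alike, and the KO level was near that of WT. A total of 7 genes were higher and 6 lower, 2038 had an unadjusted p under 0.05, and DESeq2 called 135. Glucocorticoid-induced genes rose as a group, with a median of 0.26 and 19 of 21 members above 0; 2 passed over all genes and 11 adjusted over the list alone. Sgk1 rose by 1.19 ± 0.095 and Tsc22d3, a glucocorticoid-induced leucine zipper gene, by 0.54 ± 0.056 (adjusted p = 0.0158 and 0.0485), while Arrdc2 at 0.75 ± 0.085 and Ddit4 at 0.72 ± 0.096 passed adjusted over the list alone. The list call held with an estimated correlation (adjusted p = 0.0338), as did that of the sex-linked list (adjusted p = 0.0338), whose 4 higher and 1 lower members were called both over all genes and adjusted over the list alone. The sex-linked median was 9.75 as fitted and 8.14 with Uty at its bound. The remaining called genes, chosen here after their values were seen, were the clock gene Per2 at 0.73 and the nuclear receptor gene Nr2f1 at -0.51. Rapid activity-induced genes had a median of -0.28 and 5 lower members adjusted over the list alone, led by Ier5 at -0.44 ± 0.074 and Npas4 at -2.39 ± 0.50, with 0 over all genes (edgeR) and an adjusted p = 0.785 with an estimated correlation. Without Het 2 that median was 0.0028 and the call was lost. Neocortex markers were lower with a median of -0.79, 2 of 12 adjusted over the list alone (Rprm at -0.42 ± 0.093 and Tbr1 at -0.75 ± 0.19; adjusted p = 0.785 with an estimated correlation). Without Het 2, the library with the high neocortex score, the median of neocortex markers was -0.25 and the call held. Uty was lost without KO 1 or KO 2 (adjusted p up to 0.0651), and Kcnj2, Zrsr1, Tsc22d3, Per2 and Nr2f1 each passed in 1 of the 6 fits with a library left out, the one without Het 1 (adjusted p up to 0.53). Sgk1 was lost without WT 1, Het 2 or KO 1 (adjusted p up to 0.1). Against 13 called genes, leaving out Het 1 gave 1211, Het 2 gave 8, WT 1 gave 7, WT 2 gave 8, KO 1 gave 6 and KO 2 gave 7. The blocked fit, the fit of the 2 groups alone and the fit without X and Y genes called 7, 7 and 3.

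WT fear against WT home cage asked which genes follow fear conditioning after 30 min. The only control was the home cage, so effects of handling, context and shock cannot be told apart. Genes that neurons switch on within minutes of activity rose. Egr2, a zinc finger transcription factor, rose 25.6-fold (4.68 ± 0.49), and the AP-1 genes Fos, Junb and Fosb rose 5.83-fold, 2.85-fold and 3.99-fold. Arc, which encodes a cytoskeletal regulator of synaptic strength, went from 76.4 ± 24 CPM (n = 5) to 279 ± 50 CPM (n = 3; SD), 3.95-fold with batch taken into account. Fos went from 4.94 ± 1.8 to 25 ± 7.7 CPM. The nuclear receptor genes Nr4a1 and Nr4a2 rose 3.39-fold and 2.49-fold, Egr1 2.87-fold and the ERK phosphatase gene Dusp6 1.98-fold. The serotonin receptor gene Htr1a, which is in neither activity-induced list, rose 2.74-fold. Its log2 difference ran from 0.288 to 1.715 over 28 alternatives. The edgeR adjusted p was 0.000427 for Egr2, 0.00151 for Fos, 0.00211 for Arc and at most 0.0136 for the other genes just named. Of the 27 rapid activity-induced genes 25 lay above 0, with a median of 0.71; 10 rose over all genes, and 16 were higher and 1 lower adjusted over the list alone. The list call held with an estimated correlation (adjusted p = 0.0255). Delayed activity-induced genes had a median of 0.19, with 5 higher and 1 lower over all genes and 9 higher and 2 lower adjusted over the list alone, led by Dusp6, Nr4a2, the kinase gene Sik1 (1.41 ± 0.25) and Nr4a3 (0.64 ± 0.12). Its adjusted p = 0.0762 with an estimated correlation. Values that did not pass were Dusp1 at 0.76 ± 0.24, the transcription factor gene Npas4 at 0.93 ± 0.38, the neurotrophin gene Bdnf at -0.19 ± 0.13, and the glucocorticoid-induced Fkbp5 at 0.12 ± 0.14 and Sgk1 at -0.022 ± 0.15.

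Genes that were lower after fear in WT included a dynein of motile cilia and a smooth muscle actin. The dynein gene Dnah11 fell by 4.17 ± 0.72 and the smooth muscle actin gene Acta2 fell by 2.98 ± 0.54. Spag17, of the ciliary central apparatus, and Ccdc33 had 1 and 3 reads in the 3 WT fear libraries, and were 50.1-fold (95% counting interval 8.87 to 1990) and 15.3-fold (5.15 to 75.1) higher in WT home cage. The mitochondrial arginase gene Arg2 fell by 2.37 ± 0.39, the protease inhibitor gene Serpinb8 by 1.61 ± 0.21, and Amigo2, an adhesion protein gene of CA2 neurons, by 1.65 ± 0.25. Calhm5, Srl and the monoamine oxidase gene Maoa fell by 0.90 ± 0.17, 0.83 ± 0.13 and 0.65 ± 0.12. The edgeR adjusted p of these 10 genes ran from 0.00204 to 0.0263. Markers of cell types and regions moved with the same groups, and none of their list calls held with an estimated correlation. Ependymal markers were lower with a median of -2.35, 2 of 10 over all genes and 10 adjusted over the list alone, with Ccdc153 at -4.02 ± 0.86 and Foxj1 at -2.24 ± 0.54 (adjusted p = 0.12 with an estimated correlation). Oligodendrocyte markers were lower with a median of -1.22, 10 of 15 over all genes and 15 adjusted over the list alone, with Aspa at -1.57 ± 0.33 and Mog at -1.42 ± 0.30 (adjusted p = 0.12). CA1 markers were higher with a median of 1.18, 6 of 10 over all genes and 10 adjusted over the list alone, with Mpped1 at 1.20 ± 0.23 and Gpr161 at 1.66 ± 0.33 (adjusted p = 0.111). CA2 and CA3 markers were lower with a median of -0.59, 3 of 14 over all genes, and 9 lower with 2 higher adjusted over the list alone (adjusted p = 0.111). Choroid plexus markers had a median of -1.61 with 1 of 15 lower over all genes and 4 adjusted over the list alone, led by Sostdc1 at -1.88 ± 0.37 (adjusted p = 0.263 with an estimated correlation). Interferon response genes had a median of -1.01 with 1 of 21 over all genes and 13 adjusted over the list alone, led by Irf7 at -3.39 ± 0.77 (adjusted p = 0.251), and thalamus markers a median of -0.74 with 1 and 5 of 13, led by Prkcd at -1.63 ± 0.34 (adjusted p = 0.239).

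In total 129 genes rose and 112 fell after fear in WT, 3083 had an unadjusted p under 0.05, and DESeq2 called 938. Within B1, which holds 2 WT home cage and 3 WT fear libraries, Arc (2.09 ± 0.19) and Fos (2.42 ± 0.29) rose and Ccdc153, Dnah11 and Ak7 fell, the 5 genes called there, and the medians of the rapid, CA1, oligodendrocyte and ependymal lists were 0.61, 1.01, -1.17 and -2.05. Egr2, Fos, Junb, Dusp6, Arc and Serpinb8 passed in each of the 17 fits with a library left out, and the other 14 named genes were lost without WT home cage 2 in each case, and some also without WT fear 2, WT fear 3 or KO home cage 4 (adjusted p up to 0.221). The passing list members with the smallest p that were not among those 20 genes, 25 in all, each passed in 3 to 15 of the 17 fits and were lost without WT home cage 2 and without WT fear 2 (adjusted p up to 0.328). The total count was less stable: it was 6 without WT home cage 2, 829, 95 and 124 without WT home cage 1, 4 and 5, and 793, 13 and 10 without WT fear 1, 2 and 3. It was 655, 397, 32 and 114 without KO home cage 1, 3, 4 and 5, and 89, 95 and 56 without KO fear 2, 3 and 4, libraries that enter through the batch term and the shared spread. With tissue marker scores as covariates 0 genes passed by edgeR, and the log2 differences were 3.92 ± 0.79 for Egr2, 2.24 ± 0.45 for Fos, 1.65 ± 0.45 for Arc, 0.97 ± 0.28 for Junb, 0.76 ± 0.33 for Nr4a1, 0.64 ± 0.31 for Egr1 and 0.50 ± 0.67 for Npas4, with a rapid list median of 0.49.

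**Figure D3:**
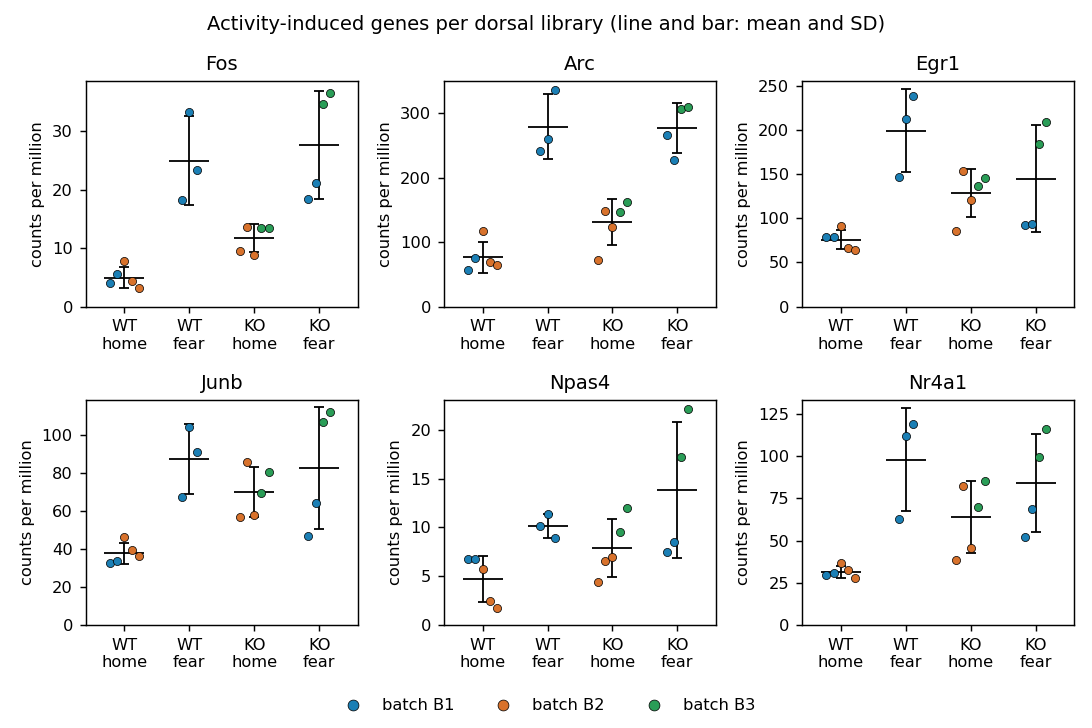
CPM of Fos, Arc, Egr1, Junb, Npas4 and Nr4a1 in the 17 dorsal libraries by group, coloured by batch, with a line and bar for the mean and SD. Arc averaged 76.4 CPM in WT home cage and 279 CPM in WT fear, against 131 CPM and 278 CPM in KO.

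KO fear against KO home cage put the same question to mice without the enzyme. Of the 5 genes with the smallest p-values 3 were rapid activity genes that rose in WT, and none of the 5 passed. Fos stood at 1.28 ± 0.25 (2.43-fold), Egr2 at 1.93 ± 0.38 (3.8-fold) and Arc at 1.16 ± 0.23 (2.23-fold). The antiproliferative gene Btg2, also a member of the rapid list, stood at 0.61 ± 0.12. Tmem38b, a cation channel gene of the endoplasmic reticulum, stood at 0.57 ± 0.11 (edgeR adjusted p = 0.404 for each of the 5). Fos averaged 11.8 ± 2.4 CPM in KO home cage (n = 5) and 27.7 ± 9.2 CPM in KO fear (n = 4; SD), and Arc 131 ± 36 and 278 ± 39 CPM. With edgeR 0 genes passed over all genes, 714 had an unadjusted p under 0.05 against 740 expected by chance, and DESeq2 called 6, which were Arc, Btg2, Egr2, Fos, Ranbp6 and Tmem38b. The rapid activity list was higher as a group by camera, with a median of 0.30 and 24 of 27 members above 0. Of these 0 passed over all genes and 5 were higher adjusted over the list alone, with an adjusted p = 0.0584 with an estimated correlation. The delayed list had a median of 0.12 with 3 members higher adjusted over the list alone: Tiparp at 0.64 ± 0.16, Sik1 at 0.79 ± 0.22 and Crem at 0.45 ± 0.13 (adjusted p = 0.0584 with an estimated correlation). Heat shock genes had a median of 0.096 with 3 of 17 members higher adjusted over the list alone, led by the chaperone gene Hspa5 at 0.61 ± 0.15 (adjusted p = 0.695 with an estimated correlation), a call lost without KO fear 3 (median 0.039). Other values that did not pass were Junb at 0.36 ± 0.18, Nr4a1 at 0.39 ± 0.24, Egr1 at 0.14 ± 0.22, Npas4 at 0.42 ± 0.31, Dusp1 at 0.26 ± 0.19, Bdnf at 0.10 ± 0.12, Fkbp5 at -0.21 ± 0.12 and Sgk1 at 0.22 ± 0.14. Thalamus markers were lower as a group with a median of -0.31 (adjusted p = 0.34 with an estimated correlation), and the medians of CA1, oligodendrocyte and ependymal markers were -0.34, -0.25 and 0.12. Within B3, with 2 libraries per group, Fos (1.40 ± 0.12, adjusted p = 0.0265) and Arc (0.98 ± 0.089, adjusted p = 0.0267) rose, the 2 genes called there by edgeR, and the rapid list median was 0.46. No gene was called by edgeR in any of the 17 fits with a library left out.

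KO against WT home cage asked what loss of the enzyme does in dorsal hippocampus at rest. Acss2 fell 15.3-fold and was the 1 gene that passed by edgeR. The smallest p-values among the others belonged to Epop, of a Polycomb-associated complex (0.82 ± 0.14, adjusted p = 0.141), the glycoprotein gene Gpnmb (-0.60 ± 0.13), Slfn5 (-0.91 ± 0.20), the Notch ligand gene Jag1 (-0.68 ± 0.15) and the histone H2A deubiquitinase gene Mysm1 (-0.42 ± 0.095), the last 4 with adjusted p = 0.44. An unadjusted p under 0.05 was reached by 1674 genes, and DESeq2 called 2, Acss2 and Epop. Rapid activity genes were higher in KO at rest as a group by camera, with a median of 0.21 and 20 of 27 members above 0; Fos stood at 0.99 ± 0.23, Egr2 at 1.86 ± 0.45, Junb at 0.59 ± 0.16 and Nr4a1 at 0.72 ± 0.21. These values did not pass over all genes, 5 members were higher adjusted over the list alone, and the list had an adjusted p = 0.503 with an estimated correlation. CA1 markers were higher in KO in the same comparison, with a median of 0.43 and 10 of 10 members above 0, 0 of them passing over all genes (edgeR) or adjusted over the list alone (adjusted p = 0.635 with an estimated correlation). That call was lost without KO home cage 2 (median 0.17) and without KO home cage 3 (median 0.33). With tissue marker scores the rapid list median was 0.13, with Fos at 0.77 ± 0.22, Egr2 at 1.49 ± 0.40, Junb at 0.40 ± 0.14 and Nr4a1 at 0.39 ± 0.17. Endothelial markers were lower as a group with a median of -0.51, 15 of 15 members below 0, and 7 lower adjusted over the list alone, led by Flt1 at -0.58 ± 0.14 and Pecam1 at -0.61 ± 0.16 (0 over all genes by edgeR, adjusted p = 0.503 with an estimated correlation). Without a batch term the endothelial median was no longer negative. Mural cell markers had a median of -0.20 with 4 of 12 lower adjusted over the list alone, led by Rgs5 at -0.65 ± 0.15 (adjusted p = 0.503 with an estimated correlation). Ribosomal protein genes had a median of 0.37 and dentate gyrus markers one of -0.28, with 0 members of either passing adjusted over the list alone (edgeR; adjusted p = 0.503 for both with an estimated correlation). Within B2, with 3 libraries per group, Acss2 fell by 4.01 ± 0.11 (adjusted p = 5.83e-06) and the rapid, CA1, endothelial and ribosomal medians were 0.17, 0.64, -0.59 and 0.32. Leaving out KO home cage 3 gave 585 called genes and leaving out KO home cage 1 gave 2.

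KO against WT after fear gave the largest count of the 8 comparisons, with 1510 genes higher and 1788 lower in KO by edgeR. Genes with the smallest p among the higher ones were Phkg1, a subunit of phosphorylase kinase (0.72 ± 0.12), Arg2 (2.26 ± 0.39), the interferon-inducible Mndal (1.73 ± 0.30) and Serpinb8 (1.22 ± 0.22). Among the lower ones they were Spry4, an inhibitor of ERK signalling (-0.93 ± 0.14), Fam117b (-0.75 ± 0.12), the glypican gene Gpc4 (-1.13 ± 0.18) and the splicing factor gene Sf3a2 (-1.16 ± 0.19). The edgeR adjusted p was 0.0155 for each of the 8. Egr1 was lower in KO after fear (-0.90 ± 0.24, adjusted p = 0.0212), and so was Fkbp5 (-0.48 ± 0.14, adjusted p = 0.0256). Junb at -0.56 ± 0.20, Nr4a1 at -0.66 ± 0.26, Fos at -0.28 ± 0.28, Arc at -0.26 ± 0.25, Npas4 at -0.015 ± 0.38, Dusp1 at -0.21 ± 0.23, Bdnf at 0.30 ± 0.13 and Sgk1 at 0.20 ± 0.15 did not pass. The rapid list as a whole was not called (median -0.21, camera adjusted p = 0.0563). Among histone acetylation enzymes and readers, the acetyltransferase genes Crebbp (-0.70 ± 0.18) and Ep300 (-0.75 ± 0.20) and the bromodomain gene Brd3 (-0.47 ± 0.10) fell, with edgeR adjusted p from 0.0155 to 0.0197. Of the 31 members 2 were higher and 8 lower over all genes, and 2 and 9 adjusted over the list alone. Of all genes tested, 22.3% were called in this comparison. The list was not called by camera (adjusted p = 0.437), and its median of 0.048 differed in sign from its mean of -0.074. The acetyl-CoA list was not called either (median 0.12, adjusted p = 0.437), with the fatty acid synthase gene Fasn lower at -0.64 ± 0.18 and Naa10, Acot7 and Acat1 higher at 0.63 ± 0.17, 0.45 ± 0.13 and 0.37 ± 0.11. Of its 30 members 5 were higher and 2 lower over all genes, and 6 and 3 adjusted over the list alone.

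Several lists moved between the genotypes after fear, and none of these calls held with an estimated correlation. Ribosomal protein genes were higher in KO with a median of 0.83, 56 of 79 over all genes and 68 adjusted over the list alone, led by Rps7 at 1.01 ± 0.19 (adjusted p = 0.542 with an estimated correlation). Synaptic and memory genes were lower with a median of -0.36, 16 of 37 over all genes and 17 adjusted over the list alone, among them the glutamate receptor genes Grin2b at -1.23 ± 0.28 and Grm5 at -0.70 ± 0.17 and the adhesion gene Nlgn2 at -0.86 ± 0.19 (adjusted p = 0.632). Ependymal markers were higher with a median of 2.57, 10 of 10 by either count, led by Ccdc153 at 4.26 ± 0.83. Choroid plexus markers had a median of 2.21 with 8 of 15 higher over all genes and 13 adjusted over the list alone, led by Sostdc1 at 1.90 ± 0.37. The choroid plexus score was 1.46 in KO fear 2 and -0.391 to 0.453 in the other KO fear libraries, and -1.7 in WT fear 2 and -0.695 and -0.125 in the other WT fear libraries; the median was 1.59 without KO fear 2 and 1.72 without WT fear 2, and the call held. Oligodendrocyte markers had a median of 0.94 with 11 and 15 of 15, led by the myelin basic protein gene Mbp at 1.12 ± 0.26. CA1 markers were lower with a median of -1.12, 8 of 10 over all genes and 9 adjusted over the list alone, led by Gpr161 at -1.62 ± 0.35. CA2 and CA3 markers had a median of 0.45, with 4 of 14 higher and 1 lower over all genes and 7 higher and 2 lower adjusted over the list alone, led by Amigo2 at 1.23 ± 0.25. Each of these 5 marker lists had an adjusted p = 0.542 with an estimated correlation. Within B1, with 3 WT and 2 KO libraries, 2362 genes were called and the medians of the ribosomal, ependymal, oligodendrocyte and CA1 lists were 0.87, 2.49, 0.96 and -1.39. Apart from Acss2, the named genes were lost without WT fear 2, WT fear 3 or KO fear 2, and Egr1, Fkbp5, Fasn and Acat1 also without KO fear 1 (adjusted p up to 0.251 over the genes named here); the count was 2, 1, 1 and 2068 in these 4 fits. The blocked fit called 1 gene, the fit with tissue marker scores 1, the GC and length offset 2105 and the fit without a batch term 1544, while 5781 genes had an unadjusted p under 0.05 and DESeq2 called 4055.

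The interaction asked whether the fear difference itself depended on genotype. A total of 29 genes had a more positive fear difference in KO and 42 a more negative one, 40.8% higher against 30% of the 130 genes called with RLE scaling. Junb (-1.15 ± 0.22) and Egr1 (-1.38 ± 0.27) changed less after fear in KO than in WT (edgeR adjusted p = 0.042 for both). Further genes with a more negative fear difference in KO were Nr4a2 (-1.39 ± 0.25), the transcription factor gene Bhlhe40 (-1.47 ± 0.23), Dusp6 (-0.86 ± 0.15), Spry4 (-0.87 ± 0.16), Htr1a (-1.38 ± 0.26), Klf16 (-0.97 ± 0.17), the AMPA receptor auxiliary subunit gene Cacng3 (-1.12 ± 0.20), Irf2bp2 (-0.60 ± 0.11), Vstm2l (-1.10 ± 0.20) and Gpr161 (-2.04 ± 0.38). More positive in KO were Serpinb8 (1.61 ± 0.23), Dnah11 (4.60 ± 0.78), Mndal (1.98 ± 0.34), the caldesmon gene Cald1 (0.76 ± 0.13), Arg2 (2.41 ± 0.43), Amigo2 (1.49 ± 0.28), Il1rap (0.65 ± 0.12), the calcium sensor gene Scgn (2.01 ± 0.38), Acta2 (3.03 ± 0.58) and Srl (0.78 ± 0.15). The adjusted p of these 20 genes ran from 0.038 to 0.0406. Nr4a1 (-1.37 ± 0.30, adjusted p = 0.0507), Fos (-1.26 ± 0.32, adjusted p = 0.0661), Arc (-0.83 ± 0.29, adjusted p = 0.126), Npas4 (-0.50 ± 0.42), Dusp1 (-0.50 ± 0.26), Bdnf (0.29 ± 0.15), Fkbp5 (-0.33 ± 0.16), Sgk1 (0.24 ± 0.17) and Acss2 (0.40 ± 0.14) did not pass.

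Rapid activity genes as a list had a lower fear difference in KO by camera, with a median of -0.46 and 21 of 27 members below 0. Egr2 (-2.75 ± 0.53, passing in 4 of 17 fits with a library left out), Junb and Egr1 passed over all genes, and 12 were lower and 1 higher adjusted over the list alone. The list's adjusted p = 0.239 with an estimated correlation, and its median was -0.49 and -0.46 along the 2 routes within batches. With tissue marker scores as covariates its median was -0.076. In the same contrast CA1 markers had a median of -1.46 (4 lower over all genes, 10 of 10 adjusted over the list alone), ependymal markers of 2.29 (1 and 10 of 10 higher) and oligodendrocyte markers of 1.07 (0 and 15 of 15 higher, edgeR). Their adjusted p with an estimated correlation was p = 0.229, p = 0.229 and p = 0.265. An unadjusted p under 0.05 was reached by 3238 genes, and DESeq2 called 907. Each of the 22 named genes passed in 4 to 7 of the 17 fits with a library left out. The count of 71 was 664, 0, 3, 1 and 0 without WT home cage 1 to 5, and 1007, 0 and 0 without WT fear 1 to 3. It was 894, 5, 102, 0 and 0 without KO home cage 1 to 5, and 0 without any of KO fear 1 to 4. With edgeR 0 genes passed in the blocked fit, with tissue marker scores, without a batch term and along both routes within batches, and 400 and 399 passed without the count filter and with the GC and length offset.

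**Figure D4:**
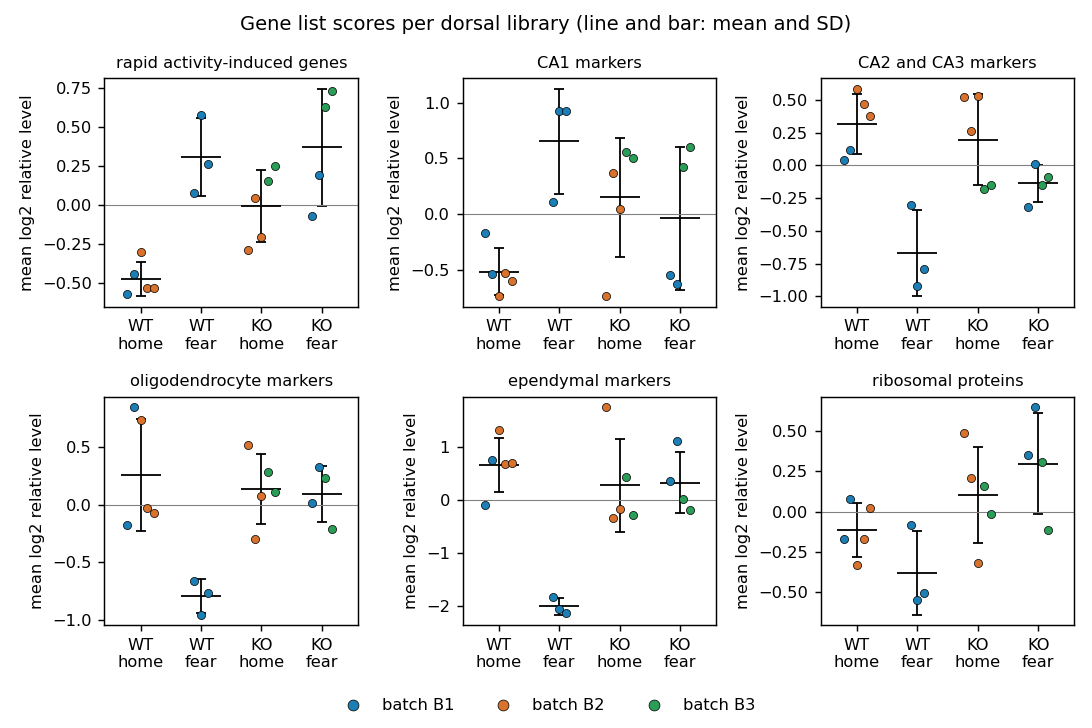
Mean log2 level of 6 gene lists, relative to the mean over the 17 dorsal libraries, in each library by group, coloured by batch, with a line and bar for the mean and SD. The 3 WT fear libraries have ependymal scores between -2.14 and -1.84, and the other libraries lie between -0.349 and 1.75.

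The KO effect at rest could be set side by side in the 2 experiments. Acss2, the 1 gene called in dorsal home cage, was also lower in whole hippocampus. Of the 5 genes called in whole hippocampus that were tested in both, 2 (40%, exact 95% interval 5.27 to 85.3%) had the same sign in the dorsal libraries, but the 4 besides Acss2 are Y-linked genes that separated the sexes in whole hippocampus, so this share does not bear on agreement of a KO effect. At an unadjusted p under 0.01 the 2 experiments shared 3 genes, named here after their values were seen: Acss2 and the X-linked histone demethylase gene Kdm6a were lower in both, and the apolipoprotein gene Apoa2 was higher in both. Kdm6a escapes X inactivation, so its whole hippocampus value cannot be told apart from sex. Chance would give 1.02 lower and 0.796 higher among the 14700 genes tested in both. Of the 293 dorsal genes at that threshold 68 had the same sign in whole hippocampus (23.2%, exact 95% interval 18.5 to 28.5%), and of the 183 whole hippocampus genes 56 had the same sign in dorsal libraries (30.6%, 24 to 37.8%). Genes are not independent replicates, so these intervals are too narrow. Most genes at that threshold thus had opposite signs in the 2 experiments. Sex and KO cannot be told apart in whole hippocampus, so these shares do not isolate a KO effect, and their cause was not tested. Histone acetylation enzymes and readers, genes next to Acss2, astrocyte, oligodendrocyte precursor, integrated stress response and C57BL/6 substrain lists were not called by camera in any of the 8 comparisons.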

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

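The tests of the sex-linked genes and of the home cage level of activity genes were chosen only after those results were seen, as was the count of splits with the batch make-up of the real one, and the fits with tissue marker scores, with the GC and length offset, with thinned libraries and along routes within batches were added after the data were seen.

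Fear differences that differed between the genotypes, by a test of the difference itself, were found for 22 named genes. Apart from Junb and Egr1, they were named for having the smallest p in this same contrast. Each passed in 4 to 7 of the 17 fits with a library left out. In the blocked fit, without a batch term, with tissue marker scores and along both routes within batches 0 genes passed by edgeR. KO minus WT, the log2 fear difference was -1.15 for Junb, -1.38 for Egr1, -1.47 for Bhlhe40, -0.86 for Dusp6, -0.97 for Klf16, -1.39 for Nr4a2, -1.12 for Cacng3, -0.87 for Spry4, -0.60 for Irf2bp2, -1.10 for Vstm2l, -2.04 for Gpr161 and -1.38 for Htr1a. It was 1.61 for Serpinb8, 4.60 for Dnah11, 1.98 for Mndal, 0.76 for Cald1, 2.41 for Arg2, 1.49 for Amigo2, 0.65 for Il1rap, 2.01 for Scgn, 3.03 for Acta2 and 0.78 for Srl. The medians of 15 lists differed by camera in the same way: rapid activity genes -0.46, synaptic and memory genes -0.28, interneuron markers -0.30, CA1 markers -1.46, ventral hippocampus markers -1.17 and neocortex markers -0.20. On the positive side were interferon response genes at 0.87, oligodendrocyte markers at 1.07, microglia markers at 0.37, endothelial markers at 0.66, mural cell markers at 0.51, choroid plexus markers at 1.97, ependymal markers at 2.29, CA2 and CA3 markers at 0.61 and ribosomal protein genes at 0.48. Of the 15 calls 0 held with an estimated correlation, where camera called 4 of 256 list tests in all and fry 35.

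In 13 of 240 groups of 4 or 5 libraries a single library lay far from the others, where chance gives about 12. Among genes these were Fkbp5 at 56.5 CPM in WT home cage 2 (others 75.5 to 81.9), Maoa at 62.7 CPM in WT home cage 2 (others 50 to 53.2), Fosb at 5.33 CPM in WT home cage 3 (others 3.48 to 3.89), Amigo2 at 33.4 CPM in KO fear 2 (others 22.1 to 23.5), Ccdc33 at 3.17 CPM in KO home cage 1 (others 0.957 to 1.47) and Gpc4 at 19.1 CPM in KO home cage 1 (others 24.3 to 26). Among mean log2 list scores, WT home cage 1 stood at -0.16 for sterol and fatty acid synthesis (others 0.0796 to 0.129), 0.28 for ventral hippocampus (others -0.619 to -0.464) and 1.09 for striatum markers (others -0.31 to -0.026). WT home cage 2 stood at 0.27 for astrocyte markers (others -0.114 to -0.0148), KO home cage 4 at 1.21 for blood markers (others -0.454 to -0.0176), KO home cage 1 at 0.34 for thalamus markers (others -0.111 to -0.0144) and KO fear 1 at -0.22 for neocortex markers (others -0.0946 to -0.0698).

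The first pattern weighed is the difference of sex-linked genes between KO and WT whole hippocampus. An effect of the deletion is argued against by the dorsal WT libraries, the lowest of which held 82.8 CPM of Ddx3y with both copies of Acss2 intact. Exchanged genotype labels are argued against by Acss2, whose lowest WT or Het level was 4.44 times the highest KO level. Animals of different sex remain. WT libraries held Xist at 663 to 677 CPM and 0 reads of Ddx3y, the pattern of female mice. KO libraries averaged 0.141 CPM of Xist and 95.3 CPM of Ddx3y, the pattern of males. A set of 4 X-linked genes that escape inactivation had a median log2 change of -0.32 in KO, the direction of female WT and male KO mice. None of the 4 passed over all genes (edgeR adjusted p from 0.633 to 0.774). Sex and KO were then confounded in whole hippocampus, so other differences between these groups may be of either origin. The same holds for KO against Het, since Het libraries resembled WT in the sex-linked genes. Het and WT did not differ in this way.

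The second pattern is the interaction of genotype and fear. With tissue marker scores in the fit, the rapid list median went from -0.46 to -0.076 (16.8% kept, 21 of 27 members with the same sign, median standard error from 0.295 to 0.452), and the median size of 62 other genes from 1.12 to 0.40 (36.1% kept, 59 with the same sign, standard error from 0.222 to 0.314). Uneven sampling of hippocampal subfields and adjoining tissue is therefore a candidate explanation for most of its size, although group and batch account for 82.6% and 75.6% of the scores' variance, so the same fit can also remove an effect of genotype. An additive batch shift as the whole cause of the rapid list difference is argued against by medians of -0.46 and -0.49 along the 2 routes within batches. Each route sets a difference in 1 batch against a difference in another. A fear or genotype difference that itself varies between batches is therefore not covered. Both routes also use the same 3 WT fear libraries, all of B1. Of 100 splits 2 gave as many genes as 71, the other of them 2315, which points to a structure of the samples, and only 3 of the 100 have the batch make-up of the real one, too few to exclude chance within batches. Whether KO mice responded less or started higher cannot be told apart, since the rapid list was 0.21 higher in KO at rest (0.13 with tissue marker scores) and -0.21 after fear, and a smaller response to fear without ACSS2 stays open.

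The third pattern is the count of 3298 genes between KO and WT after fear. Tissue marker scores took the median size of 3263 called genes from 0.62 to 0.19 (30.6% kept, 3008 with the same sign, standard error from 0.174 to 0.252). Tissue sampling would give such a fall and stays a candidate explanation. The scores were chosen after the data were seen, from lists that differed in this same comparison, and they follow group and batch. The fall would therefore also come if they removed an effect of genotype, so the share due to tissue is not settled. Depth is argued against by 2958 genes called in libraries thinned to equal depth, 2682 of them among the 3298. GC content or gene length cannot be told apart from the groups, because 2105 genes were called with the offset, 1528 of them among the 3298. Of 35 splits of the 7 libraries 1, the real one, gave as many genes, and the highest other split called 2429. Of these splits 10 have the batch make-up of the real one, with at most 51 genes in the others, which are too few for a share under 0.05. An effect of genotype after fear stays open.

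Splits of the libraries were also counted for the remaining dorsal comparisons. For WT fear 1 of 56 splits, the real one, called as many genes as 241, and the highest other split called 1. The 10 splits with the real batch make-up are too few for a share under 0.05; the other 9 called 0 genes by edgeR, and 1 of them had 3197 genes at an unadjusted p under 0.05 against 3083. For KO fear, where 0 genes were called by edgeR and DESeq2 called 6, the count at an unadjusted p under 0.05 was compared: 39 of 99 splits reached 714 and the highest gave 3275. For KO against WT home cage 5 of 100 splits called at least 1 gene and the highest called 2361. Such splits count how many genes are called and not which, so they leave the size of these 2 counts open to chance and not the call of Acss2, at 3.87 to 5.85 CPM in KO and 57.6 to 71.3 CPM in WT. Splits with several times the real count point to a structure of the samples other than the groups.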

How the results depend on the processing

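The tissue marker, choroid plexus score, GC and length, crossed block, thinned library, without-B1, without X and Y gene and within-batch route settings were chosen after the data were seen; where no reason is given, the cause was not tested.

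In whole hippocampus, KO against WT went from 6 genes to 19 with DESeq2 and to 1 without X and Y genes, by construction. Het against WT went from 0 with edgeR (2145 at an unadjusted p under 0.05) to 142 with DESeq2, 3 without the count filter, and 1 each with robust dispersions, the choroid plexus score and the crossed block. KO against Het went from 13 to 135 with DESeq2, 23 without the filter, 21 with robust dispersions, 24 with the crossed block, 7 with the replicate block, 7 with the 2 groups alone and 3 without X and Y genes. Leaving out 1 library gave 5 to 7, 0 to 1424 and 6 to 1211 genes, the last 2 highest without Het 1.

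WT fear went from 241 genes to 938 with DESeq2, 528 without the filter, 592 with the GC and length offset, 712 without a batch term, 15 with the replicate block, 19 with the 2 groups alone, 5 within B1 and 0 with tissue scores by edgeR. KO fear went from 0 with edgeR (714 at an unadjusted p under 0.05) to 6 with DESeq2, 2 within B3, 1 without a batch term and 2 with tissue scores. KO against WT home cage went from 1 to 2 without the filter, with DESeq2 and without a batch term. KO against WT after fear went from 3298 to 2105 with the offset, 1544 without a batch term, and 1, Acss2, with the replicate block and with tissue scores. The interaction went from 71 to 130 with RLE, 400 without the filter, 907 with DESeq2, 399 with the offset, and 0 by edgeR with the replicate block, no batch term, tissue scores and both within-batch routes (3238 at an unadjusted p under 0.05). Leaving out 1 library gave 6 (WT home cage 2) to 829 (WT home cage 1), 0 to 0, 1 to 585 (KO home cage 3), 1 (WT fear 3) to 4610 (KO home cage 3) and 0 (WT home cage 2, among others) to 1007 (WT fear 1) genes. A lone library left in a group was assumed to vary like the other groups.

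Replicate numbers did not pair the dorsal samples. Libraries of different dorsal groups with 1 number had a median correlation of -0.0723, with 3 of 22 over 0.1. In whole hippocampus this correlation was 0.388 for WT with Het, -0.678 for WT with KO and -0.391 for Het with KO. With 2 libraries per group, deviations from the group mean mirror each other. Exchanging the numbers of 1 group thus only turns the sign, so pairing there was not settled. List calls went from 90 to 4 with an estimated correlation and 35 with fry.

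Signs reversed mostly with tissue scores, which by construction remove differences of CA1, CA2 and CA3, oligodendrocyte and ependymal markers; for the other lists the cause was not tested. In WT fear the medians became -0.203 for synaptic, 0.104 for oligodendrocyte, 0.371 for choroid plexus, 0.226 for ependymal, -0.202 for CA1, -0.283 for ventral hippocampus and 0.259 for ribosomal genes, and that of interneuron markers in dorsal WT fear vs home cage -0.0776. In KO against WT after fear they became -0.306 for oligodendrocyte, -0.128 for ependymal, 0.208 for CA1 and 0.0683 for ventral markers. In the interaction they became 0.166 for synaptic, -0.371 for oligodendrocyte, -0.28 for choroid plexus, -0.115 for ependymal, 0.0116 for interneuron, 0.0928 for CA1, 0.124 for ventral and -0.171 for ribosomal genes, and Gpr161 became 0.091. Striatum markers in KO fear became 0.0448 with the 2 groups alone, 0.0403 within B3 and 0.0459 without B1, and CA1 markers 0.000646 without B1. Endothelial markers in KO against WT home cage became 0.00504 without a batch term. Over the libraries left out in turn, interferon genes in Het against WT ran from -0.277 to 0.0103 (without Het 1), endothelial markers from -0.0393 (without Het 2) to 0.293, meningeal fibroblast markers in whole hippocampus Het vs WT from -0.00183 (without Het 2) to 0.593, and, in KO against Het, rapid activity genes from -0.52 to 0.0028 (without Het 2).

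For named genes 2367 values kept direction and side of the threshold, 562 no longer passed, 71 newly passed, 1 that passed changed sign (Gpr161) and 32 that passed neither way changed sign; for list medians 1935 kept both, 289 no longer passed and 29 reversed. Acss2 passed in each alternative of the 4 comparisons with KO against WT or Het. WT fear libraries, at 5362773 to 9109104 counts, limit what can be seen of genes with few reads.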

Other observations

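The comparisons of single libraries and the comparison of WT fear genes with KO libraries below were chosen only after results were seen.

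Genes that differed between WT fear and WT home cage could be followed into KO libraries that share no batch or library with the WT ones. Such genes can include ones that follow the tissue markers, which also differed between these WT groups. WT fear genes were chosen from WT libraries alone and read in KO fear against KO home cage within B3. Of 10 rapid activity genes with an unadjusted p under 0.001 in WT, 10 had the same sign in KO (exact 95% interval 69.2 to 100%), with a median log2 difference of 1.56 in WT, where selection by p inflates it, and 0.53 in KO. Of the 132 other genes 81 had the same sign (61.4%, 52.5 to 69.7%), with a median, over higher and lower genes together, of -1.25 in WT and -0.0428 in KO. At an adjusted p under 0.05 in WT, 15 of 19 had the same sign (78.9%, 54.4 to 93.9%), 5 of them in the rapid list. Genes are not independent replicates, so the intervals are too narrow.

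Levels of 5 genes in single whole hippocampus libraries are given here. The choroid plexus transthyretin gene Ttr stood at 8.1 and 2320 CPM in WT, 13.3 and 871 CPM in Het and 3630 and 7.8 CPM in KO. Npas4 stood at 15.8 and 15.3 CPM in WT, 22.8 and 71.5 CPM in Het and 7.96 and 10.3 CPM in KO. Alas2 stood at 32.2 and 58.4 CPM in WT, 2.34 CPM in each Het library and 5.46 and 3.65 CPM in KO. Eps8l1 stood at 8.83 and 7 CPM in WT, 23.5 and 20 CPM in Het and 1.09 and 1.73 CPM in KO. In the dorsal home cage Eps8l1 averaged 4.83 ± 1.2 CPM in WT and 5.92 ± 3.6 CPM in KO (SD, n = 5 each), a difference that did not pass. Sgk1 stood at 124 and 143 CPM in WT, 77.4 and 77.9 CPM in Het and 189 and 164 CPM in KO.

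In the dorsal libraries, CA1 marker scores of WT fear 1 to 3 were 0.11, 0.93 and 0.92, and their ependymal scores -1.84, -2.05 and -2.14. WT fear 2 had a ventral hippocampus score of 1.60. KO fear 2 had a choroid plexus score of 1.46 and Ttr at 445 CPM.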
